A study of Mus musculus with 10 samples.

How the data were processed

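Gene expression was measured in mouse embryonic stem cells on 10 one-colour Agilent arrays of 6 groups, and each group is 1 cell line. Per the labels' protocols, the cells grew without feeder cells in medium with serum and leukaemia inhibitory factor, and total RNA was amplified and labelled with Cy3. The replicates were not stated to be separate cultures, so p-values measure only the spread between these arrays, which may be technical.

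The scanner files hold 1 fluorescence intensity per spot. Per the file headers, they were made by Agilent Feature Extraction 10.7.3.1, which removed background trends within each array, and the intensities were not normalized between arrays. Probes are 60 bases long with coordinates on mm9, per the file headers. Per the submitters' processing notes limma was used as well, with a version not given in the sources used here. The value table deposited by the authors was set against the scanner intensities. Its columns correlated with log2 intensity at r of at least 0.999 across spots and each had a median of 4.243. They differed from quantile-normalized log2 intensities by at most 0.246. These values were read as log2 values scaled between arrays by the authors and not centred per gene, with the exact scaling unknown, and it served as an alternative.

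Slides and scan days were read from the scanner files, and each slide was scanned on a day of its own. Slide 1 held J1 replicate 1, PRDM14_DNMT3B replicate 1, Dnmt3b_KO replicate 1, Dnmt1_KO and TKO. Slide 2 held the second replicates of J1, PRDM14_DNMT3B and Dnmt3b_KO. PRDM14 replicates 1 and 2 lay alone on slides 3 and 4. The comparisons of PRDM14 with other groups therefore have no value within a slide, and slide and group cannot be told apart there. Within slides 1 and 2 the arrays were scanned in 2 passes of the same day. On slide 1, Dnmt1_KO and TKO were scanned in another pass than J1, PRDM14_DNMT3B and Dnmt3b_KO. On slide 2, J1 was scanned in another pass than PRDM14_DNMT3B and Dnmt3b_KO. Differences from J1 within slide 2, and those of Dnmt1_KO and TKO within slide 1, therefore also cross scan passes.

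Control spots and outlier spots were left out, which left 59305 spots for 55681 probes per array before outliers were removed. The share of spots well above background ran from 50.03% to 56.03% per array, the 75th percentile of the signal from 243.1 to 337.3 intensity units, and no spot was saturated. The number of arrays limits the precision of every value. From each log2 intensity the 75th percentile of its array was subtracted, spots of 1 probe were averaged, and probes well above background on every array of at least 1 group were kept, 33116 in all. The probe with the highest mean stood for its gene, which left 23807 genes after 13 were dropped for missing values. Of these, 6145 had several probes. In PRDM14 against J1, 114 of the 3581 changed genes with several probes had another probe that passed the test in the opposite direction. Gene names came from the scanner files and were updated through the accessions of the GRCm38.p6 RefSeq table. That table matched 26582 of 28116 accessions and changed 2891 symbols, and its coordinates were not used. No mm9 annotation was used here, so exon and intron positions of probes are not given.

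All 10 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3, input read with version 1.17.8 of data.table) without covariates, with 4 residual degrees of freedom and a prior of 1.728. Dnmt1_KO and TKO have 1 array each and were assumed to vary like the other groups. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are on the log2 intensity scale. Where a probe was not well above background on any array of 1 group, the fold is a lower bound and is written "at least". It sets the bright group's mean against a dim group's mean that took, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Median shifts of gene lists are also given with such genes at their bound where this moves them. The adjusted p beside a bound is that of the fit.

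The comparisons, the alternatives, the rule for named genes and 18 gene lists with 365 symbols were fixed before the data were examined. The lists are DNA methylation enzymes, TET and base excision repair, naive pluripotency, primed epiblast, germline, FGF-ERK targets, germ cell specification, imprinted genes, the Rhox cluster, 2-cell genes, trophoblast, primitive endoderm, mesoderm, neural, fibroblast, Polycomb, p53 and stress, and housekeeping. List shifts were tested with camera of limma at a preset correlation of 0.01 between genes, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 18 lists of a comparison. Of 162 list results, 73 passed with the preset correlation and 10 with the estimated correlation. In PRDM14 against J1 these counts were 6 and 0 of 18, with 4 at an unadjusted p under 0.05 with the estimated correlation. The fry test of limma, which asks whether the members of a list moved on balance 1 way and does not compare them with other genes, was fixed beside them and passed 141. Calls in the text are those of camera at the preset correlation. Within a list, counts are also given adjusted over the list alone. Named genes were Prdm14, Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l and Xist, up to 3 members of each of the first 5 lists and 1 of every other list with the largest difference past the threshold, and the 5 largest rises and 5 largest falls without overlap between the groups. Predicted, accession-named and similar uncharacterized names were left out of the largest rises and falls. A gene named for PRDM14 against J1 was allowed in every other comparison. Uty was chosen after its values were seen, and so were Eif2s3y, Ddx3y, Mid1, Hprt and Plagl1 wherever the rule did not name them. Near-identical family members such as the Zscan4 genes may share probe signal and are reported as uncertain.

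All comparisons against J1 share the same 2 J1 arrays, too few to split. Overlaps were set beside 100 simulated pairs of unchanged groups and beside the overlap of independent lists. The fit was tested on simulated data for all 23807 genes with 200 changed genes. That is far fewer than the 9440 called in PRDM14 against J1, and with fewer changed genes the adjusted threshold is harder to pass. The recovered shares that follow therefore do not carry over to the real comparisons. In simulated PRDM14 against J1, 2% of 50 genes changed by 0.5 log2 units were recovered, 38% at 1, 76% at 2 and 82% at 3, and 9 of 108 calls were false. In simulated TKO against J1, the shares were 0%, 28%, 66% and 80%, and 7 of 94 calls were false. A simulated unchanged Dnmt3b_KO against J1 gave 0 calls by limma at the adjusted threshold and 1239 genes at an unadjusted p under 0.05. The alternatives were quantile normalization, median centring, normexp background correction with an offset of 50 under both scalings, the deposited value table, no filter or a filter on all 10 arrays, the mean of a gene's probes, a variance prior with trend, a log2 difference of at least 1 besides the adjusted p, a fit of only the 2 groups compared, blocks for replicate number and slide, and leaving out each replicate. Median centring moved the median log2 difference of all genes from -0.097 to 0.005 in Dnmt3b_KO against J1, from 0.127 to 0.249 in PRDM14 against Dnmt1_KO, and from 0.036 to 0.177 in PRDM14 against TKO. Normexp with quantile normalization moved it from -0.145 to -0.037 in Dnmt1_KO against J1. Dnmt3b_KO as the reference in place of J1, and the lists without chromosome 8 genes, were chosen after seeing the data. Both count among the alternatives of a list. In comparisons of PRDM14, PRDM14_DNMT3B, Dnmt1_KO and TKO with J1, several ranges therefore end at a value against Dnmt3b_KO, a different reference line.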

Results

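Gene expression was measured on 10 arrays of mouse embryonic stem cells. J1, a widely used line, gave 2 arrays, and so did each of 3 lines labelled PRDM14 (PRDM14 overexpressed), PRDM14_DNMT3B (DNMT3B1 added as well) and Dnmt3b_KO (knockout). Dnmt1_KO and TKO, a triple knockout of Dnmt1, Dnmt3a and Dnmt3b, gave 1 array each and have no replicates. The series asked how loss of DNA methylation through PRDM14 overexpression affects gene expression. Levels are log2 signal minus the 75th percentile of the array, errors are SD over arrays or SE of a difference, and 23807 genes were tested. Across the 18250 genes well above background on all 10 arrays, replicate arrays correlated at r of 0.9951 to 0.9977, with median differences of 0.113 to 0.159 log2 units. Dimmer genes are not covered by these values, and genes are not independent replicates. The first principal component of the same 18250 genes held 48.74% of the variance.

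The targeted genes came first. Dnmt1, the maintenance methyltransferase (mm9 chromosome 9, 20711973 to 20712341), was at 1.46 ± 0.23 (SD, n = 2) in J1, -2.68 in Dnmt1_KO and -3.15 in TKO, and fell by 4.14 and 4.61 log2 units (limma adjusted p of 0.000246 and 0.000245). Dnmt3a, a de novo methyltransferase (chromosome 12, 3914320 to 3914379), was at least 15.8-fold lower in TKO than in J1 (limma adjusted p = 7.84e-05). Dnmt3b, the other de novo methyltransferase (chromosome 2, 153513403 to 153513462), was at 7.59 ± 0.02 (SD, n = 2) in J1 and at 1.66 ± 0.05 (SD, n = 2) in Dnmt3b_KO. It fell by 5.93 log2 units there and fell by 5.59 in TKO (limma adjusted p of 2.33e-05 and 7.84e-05). Dnmt3b also fell by 2.56 log2 units in the PRDM14 line and fell by 3.45 in PRDM14_DNMT3B (limma adjusted p of 2.97e-05 and 2.47e-05), and its 3 probes all lay lower there. Where the probes lie relative to the deleted exons is not given in the sources used here.

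The Prdm14 probe (chromosome 1, 13103555 to 13103614) did not rise in the line labelled PRDM14. Its level was 0.01 ± 0.12 (SD, n = 2) in J1 and -4.17 ± 0.21 (SD, n = 2) in PRDM14, an 18.1-fold lower signal (limma adjusted p = 2.61e-05). In PRDM14_DNMT3B it was not above background and lay at least 16.9-fold under J1 (limma adjusted p = 2.47e-05). It rose by 1.16 log2 units in Dnmt3b_KO and 0.84 in TKO (limma adjusted p of 0.00334 and 0.0121). Whether this probe or those of Dnmt3b detect the transgenes is not given in the sources used here, so the overexpression itself was not measured, and groups are named as labelled. Xist, the RNA that silences an X chromosome, was not above background on any array.

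**Figure D1:**
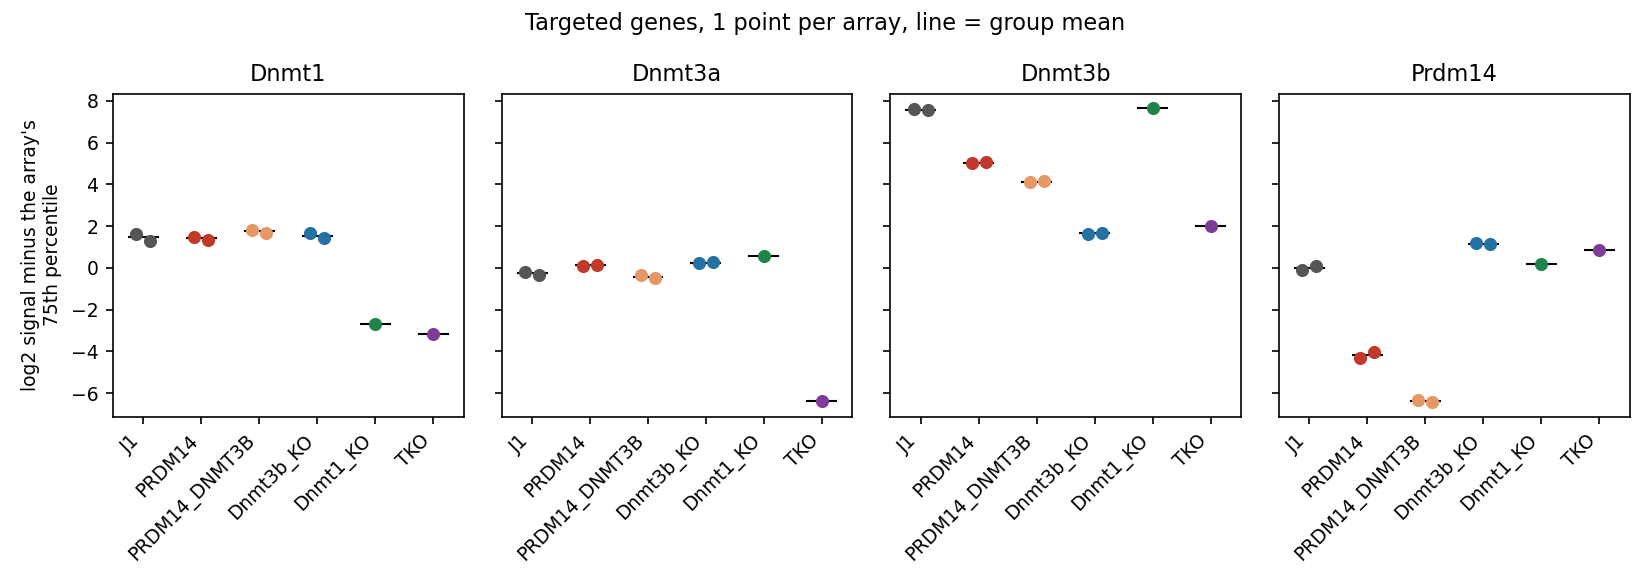
Log2 signal minus the array's 75th percentile (y axis) of Dnmt1, Dnmt3a, Dnmt3b and Prdm14 in the 6 groups (x axis), with 1 point per array and a line at the group mean. Dnmt3b lay at 7.59 in J1, 5.02 in PRDM14 and 1.66 in Dnmt3b_KO, and Prdm14 at 0.01 in J1 and -4.17 in PRDM14.

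The comparison of PRDM14 with J1 asked what overexpression changes. Genes of the 2-cell embryo rose: Zscan4c, a telomere-associated factor of that stage, rose 113-fold (6.83 log2 units, SE 0.17, 2 arrays each) and Tmem92 at least 33.7-fold (limma adjusted p of 1.93e-05 and 3.11e-05). Genes of naive pluripotency rose, among them Tdh, threonine dehydrogenase, by 2.19 log2 units, Fbxo15 by 1.83 and Tbx3, a transcription factor of self-renewal, by 1.82. Against Dnmt3b_KO as the reference, chosen after seeing the data, Tbx3 did not rise (-0.03). Among epiblast genes, Fgf5, a growth factor, fell by 4.15 log2 units and Pou3f1, a transcription factor, fell by 3.63 (limma adjusted p of 3.98e-05 and 3.43e-05). Of 23807 genes, 9440 changed, 4994 higher and 4446 lower, and of those over 2-fold 2118 were higher and 1868 lower.

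Of 18 genes of the 2-cell list tested in PRDM14 against J1, 16 rose, 0 fell and 2 did not pass, and 16 rose adjusted over the list alone. Its median difference was 4.93 log2 units, or 3.02 with dim genes at their bound (camera of limma, adjusted p = 3.04e-11; adjusted p = 0.0896 with an estimated correlation). Near-identical Zscan4 copies may share probe signal. Of 46 germline genes 29 rose, 2 fell and 15 did not pass, with 29 and 2 adjusted over the list alone, and the median was 0.86, or 0.76 with bounds (adjusted p = 1.55e-07; adjusted p = 0.0726 with an estimated correlation). Tex14, needed for the bridges between germ cells, rose at least 36.2-fold, Fkbp6, a meiosis gene, by 3.95 log2 units and Piwil2, of the piRNA pathway, by 3.47. Of 25 naive pluripotency genes 17 rose, 1 fell and 7 did not pass, with 17 and 1 adjusted over the list alone and a median of 0.95 (adjusted p = 1.4e-06; adjusted p = 0.0726 with an estimated correlation).

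Trophoblast genes went the other way in PRDM14 against J1. Of 15 tested, 2 rose and 10 fell, likewise adjusted over the list alone, with a median of -1.79, or -1.64 with bounds (adjusted p = 0.00177; adjusted p = 0.0896 with an estimated correlation), and Krt8, an epithelial keratin, fell by 4.92 log2 units. Of 14 fibroblast genes 3 rose and 8 fell, 3 and 9 adjusted over the list alone, with a median of -0.89 (adjusted p = 0.0323; adjusted p = 0.297 with an estimated correlation). Dcn, a matrix proteoglycan, was at least 11.2-fold lower, and the fibroblast call ended in 4 of 21 alternatives, a block for replicate number among them (adjusted p = 0.0727, range 7.57e-11 to 0.105). The low end of this range is against Dnmt3b_KO as the reference, chosen after seeing the data. Of 14 germ cell specification genes 9 rose and 4 fell, likewise adjusted over the list alone, with a median of 0.96 (adjusted p = 0.0378; adjusted p = 0.205 with an estimated correlation). This call did not hold against Dnmt3b_KO as the reference, chosen after seeing the data (adjusted p = 0.515). That call ended in 5 of 21 alternatives (range 0.00709 to 0.515), among them leaving out J1 replicate 1 (adjusted p = 0.0598) and, chosen after seeing the data, leaving out the genes of chromosome 8 (adjusted p = 0.097).

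The other 12 lists did not pass in PRDM14 against J1, though single members changed. Of 20 primed epiblast genes 3 rose and 10 fell, likewise adjusted over the list alone (adjusted p = 0.0629; 0.0484 without PRDM14 replicate 2 and 0.0437 without either Dnmt3b_KO replicate; passing in 8 of 21 alternatives, range 5.58e-06 to 0.12), and Grhl2 fell by 2.72 log2 units. The low end of the primed epiblast range is against Dnmt3b_KO as the reference, chosen after seeing the data. Of 17 FGF-ERK targets 5 rose and 8 fell, likewise adjusted over the list alone (adjusted p = 0.207), with Egr1, an immediate early gene, falling by 2.51. Of 32 imprinted genes 10 rose and 16 fell, likewise adjusted over the list alone (adjusted p = 0.207), and of 11 Rhox genes 6 rose and 3 fell (adjusted p = 0.284), with Rhox9 rising by 2.10. Of 21 primitive endoderm genes 5 rose and 8 fell, 5 and 9 adjusted over the list alone (adjusted p = 0.174), of 10 mesoderm genes 2 rose and 5 fell (adjusted p = 0.174), and of 11 neural genes 4 rose and 1 fell (adjusted p = 0.209). T, the mesoderm factor Brachyury, was at least 23.3-fold lower. Of 13 p53 and stress genes 2 rose and 4 fell, 2 and 5 adjusted over the list alone (adjusted p = 0.187), with Atf3 falling by 2.99, and of 11 Polycomb genes 0 rose and 1 fell (adjusted p = 0.515). Of 8 DNA methylation enzymes 2 rose and 2 fell (adjusted p = 0.411), among them Dnmt3l, the cofactor of de novo methylation, which fell by 0.88. Of 21 TET and base excision repair genes 6 rose and 3 fell (adjusted p = 0.284), with Apex1, the abasic site nuclease, rising by 1.30 and Gadd45g falling by 1.14, and of 14 housekeeping genes 2 rose and 3 fell (adjusted p = 0.765), with a median of -0.12 and, through Hprt, a mean of 0.38. For the Rhox, mesoderm, neural, Polycomb, methylation, TET and housekeeping lists the counts adjusted over the list alone were the same.

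Some facts about single genes and chromosomes stand beside the comparisons with J1. Hprt, the purine salvage enzyme, was at -2.30 ± 0.06 (SD, n = 2) in J1 and at 5.81 to 6.45 in the means of the other 5 groups, 364-fold higher in PRDM14. Genes of chromosome 8 lay 0.443 log2 units (1.36-fold, bootstrap interval 0.403 to 0.478) over the other autosomes in PRDM14 against J1, 0.375 in PRDM14_DNMT3B and 0.23 in TKO, where the last of 4 parts of equal gene number was not higher (-0.037, the others 0.29, 0.38 and 0.266). It was 0.018 in Dnmt3b_KO and -0.026 in Dnmt1_KO. Chromosome 11 lay higher by 0.218 (0.188 to 0.239) in Dnmt1_KO, and chromosome 14 lay higher than in J1 in all 5 groups, by 0.077 in Dnmt3b_KO to 0.197 in TKO. In medians per array for chromosome 14, the J1 arrays were the lowest of the 10 (-0.121 and -0.128). The Dnmt3b_KO arrays were the highest there (0.087 and 0.105), above TKO (0.066), and TKO against Dnmt3b_KO stood at -0.03. The order of the groups therefore depends on the measure. The X chromosome lay at -0.121 (-0.184 to -0.072) in PRDM14 against J1 and at -0.158 in PRDM14 against Dnmt3b_KO. Among Y-linked genes, Ddx3y fell by 4.32 log2 units and Eif2s3y by 3.37 in PRDM14 (limma adjusted p of 2.38e-05 and 0.000318), and in PRDM14_DNMT3B they were at least 51.9-fold and 231-fold lower than in J1. Interferon-inducible Gbp2 was at least 83.6-fold lower in PRDM14. PRDM14 arrays lay alone on their slides, so slide and group cannot be told apart in its comparisons, and with a block for replicate number 11421 genes changed.

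**Figure D2:**
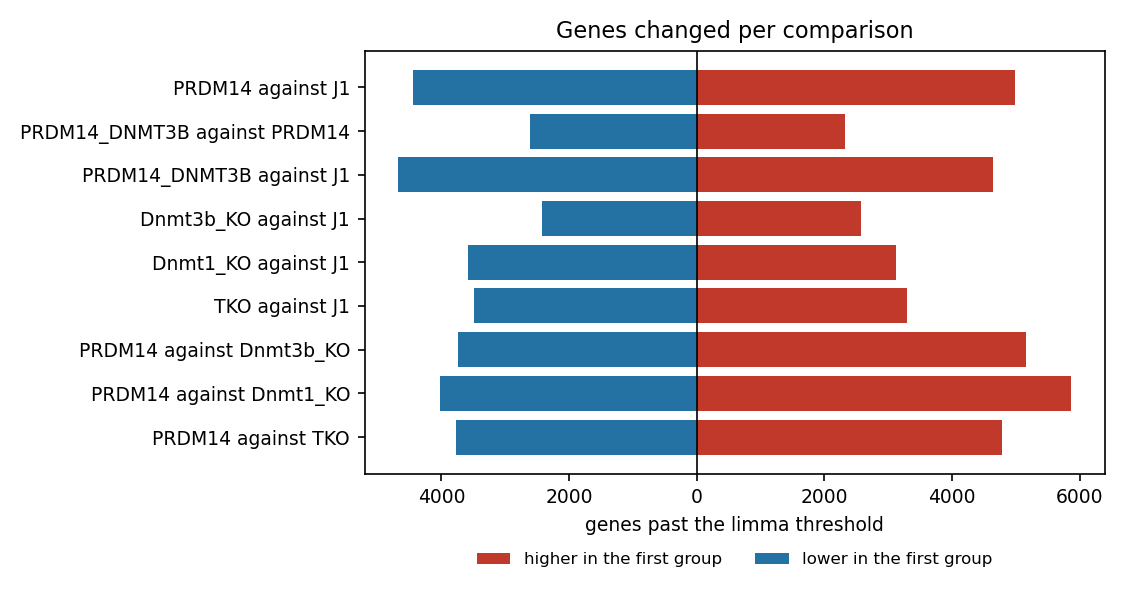
Number of genes (x axis) with higher and lower signal, as bars, in each of the 9 comparisons (y axis) at a limma adjusted p under 0.05. PRDM14 against J1 had 9440 changed genes and PRDM14_DNMT3B against PRDM14 had 4949.

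Adding DNMT3B1 was compared with PRDM14 alone, whose arrays lay on slides of their own, so slide and group cannot be told apart here. Atf3, a stress-induced factor, rose by 2.48 log2 units (SE 0.13, 2 arrays each), and of the epiblast genes Sall2 rose by 1.16 and Nodal, a signal of the early embryo, by 0.98 (limma adjusted p of 0.000747, 0.00109 and 0.00406). Egr1 rose by 3.25 (limma adjusted p = 0.000393), but of the 17 FGF-ERK targets it belongs to 3 rose and 4 fell, and the list did not pass (adjusted p = 0.911). Germline genes Fkbp6 and Gpat2 fell by 3.79 and 1.93, Rhox6, a homeobox gene of the X chromosome, fell by 3.75, and Nanog, a core pluripotency factor, fell by 0.77 (limma adjusted p of 0.000594, 0.00063, 0.000594 and 0.00441). But of the 25 naive pluripotency genes that Nanog belongs to, 2 rose and 5 fell, 2 and 6 adjusted over the list alone. Their median was -0.03, and the list did not pass with camera (adjusted p = 0.801). Of the tested genes 4949 changed, 2331 higher and 2618 lower, over 2-fold 803 and 711, and 7017 changed with a block for replicate number. Leaving out PRDM14 replicate 1 or 2 left 1909 or 2022, and leaving out PRDM14_DNMT3B replicate 1 or 2 left 2722 or 2565.

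Of 13 p53 and stress genes 10 rose and 1 fell with DNMT3B1, likewise adjusted over the list alone (median 1.03, adjusted p = 2.03e-05; adjusted p = 0.121 with an estimated correlation). Of 20 primed epiblast genes 9 rose and 1 fell, 11 and 1 adjusted over the list alone (median 0.48, 0.41 with bounds, adjusted p = 0.00104; adjusted p = 0.123 with an estimated correlation). Of 21 primitive endoderm genes 8 rose and 1 fell, 11 and 2 adjusted over the list alone (median 0.52, 0.47 with bounds, adjusted p = 0.00248; adjusted p = 0.178 with an estimated correlation), with Fst, an activin inhibitor, rising by 1.70. The 2-cell list had 0 risen and 7 fallen genes of 18, 8 fallen adjusted over the list alone (median -0.48, adjusted p = 0.00661; adjusted p = 0.314 with an estimated correlation), and with probes above background on all 10 arrays that call ended (adjusted p = 0.419, range over 20 alternatives 0.000569 to 0.419). Among 46 germline genes 3 rose and 13 fell, 3 and 14 adjusted over the list alone (median -0.19, adjusted p = 0.0236; adjusted p = 0.224 with an estimated correlation), and without PRDM14 replicate 2 that call ended (adjusted p = 0.0526, range 0.00203 to 0.0526). Of 11 Rhox genes 1 rose and 6 fell, 2 and 6 adjusted over the list alone (median -0.81, adjusted p = 0.0236; adjusted p = 0.314 with an estimated correlation), a call that ended in 1 of 20 alternatives (range 0.00399 to 0.0789). Imprinted and mesoderm genes passed with adjusted p of 0.0443 and 0.0461 (adjusted p = 0.224 for both with an estimated correlation), which became 0.108 and 0.0984 without PRDM14_DNMT3B replicate 2. The imprinted call also ended without either J1 replicate (0.0501), and the mesoderm call without PRDM14 replicate 1 or 2 (0.0528 or 0.0671) or either Dnmt3b_KO replicate (0.0589). In all they ended in 9 and 12 of 20 alternatives (ranges 0.0141 to 0.243 and 0.028 to 0.243). Trophoblast genes did not pass (adjusted p = 0.0663; 0.027 without PRDM14_DNMT3B replicate 1, range 0.027 to 0.512).

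Of the 4994 genes higher in PRDM14 than in J1, 1219 (24.4%) went the opposite way with DNMT3B1, 445 went further the same way and 3416 (68.4%) were still higher than in J1. Independent lists would give 549 and 489, and 677 of the 1219 no longer passed against J1. Of the 4446 lower genes, 1222 (27.5%) went the opposite way, 379 further the same way (independent lists 435 and 489) and 2919 (65.7%) were still lower, and 612 of the 1222 no longer passed against J1. These counts share the PRDM14 arrays, so chance deviations of those arrays enter both sides. The PRDM14 arrays also lay alone on slides 3 and 4, while J1 and PRDM14_DNMT3B shared slides 1 and 2. A slide effect on the PRDM14 arrays would give the same pattern, so it and an effect of DNMT3B1 cannot be told apart in these counts.

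PRDM14_DNMT3B against J1 asked what remained different with both transgenes. Zscan4c rose by 6.70 log2 units (SE 0.17, 2 arrays each), Tex14 at least 55.6-fold, Tbx3 by 2.32 and Jam2, an adhesion gene, by 1.75 (limma adjusted p of 2.47e-05, 2.2e-05, 0.000108 and 7.77e-05). Fgf5 fell by 3.52, Pou3f1 fell by 3.63 and Krt8 fell by 3.74 (limma adjusted p of 6.81e-05, 3.83e-05 and 2.9e-05). But of the 20 primed epiblast genes that Fgf5 and Pou3f1 belong to, 7 rose and 7 fell, 8 and 7 adjusted over the list alone. Their median was -0.16, or -0.12 with bounds, and the list did not pass with camera (adjusted p = 0.696; adjusted p = 0.728 with an estimated correlation). In all 9316 genes changed, 4641 higher and 4675 lower, over 2-fold 2080 and 1844, and with slide as a block 10563 did.

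Of 18 genes of the 2-cell list 14 rose and 1 fell in PRDM14_DNMT3B against J1, likewise adjusted over the list alone, with a median of 4.39, or 2.68 with bounds (adjusted p = 9.83e-09; adjusted p = 0.129 with an estimated correlation). The median was 4.47 within slide 1 and 4.32 within slide 2. Of 25 naive pluripotency genes 18 rose and 2 fell, likewise adjusted over the list alone (median 0.73, 0.8 within each slide, adjusted p = 2.18e-05; adjusted p = 0.113 with an estimated correlation). Of 46 germline genes 22 rose and 5 fell, 23 and 5 adjusted over the list alone (median 0.44, 0.33 with bounds, 0.5 and 0.37 within slides, adjusted p = 0.000174; adjusted p = 0.129 with an estimated correlation). Of 15 trophoblast genes 1 rose and 9 fell, likewise adjusted over the list alone (median -1.11, -1.25 and -1 within slides, adjusted p = 0.00378; adjusted p = 0.129 with an estimated correlation). Germ cell specification genes (9 rose and 4 fell of 14, 10 and 4 adjusted over the list alone), p53 and stress genes (6 and 2 of 13, 8 and 2 adjusted over the list alone) and fibroblast genes (2 and 7 of 14, likewise adjusted over the list alone) passed with adjusted p of 0.0139, 0.0146 and 0.0146. With an estimated correlation these became adjusted p of 0.129, 0.129 and 0.258, and over 22 alternatives the 3 calls ended in 1, 2 and 1 (ranges 0.0024 to 0.242, 0.0032 to 0.108 and 6.14e-11 to 0.0606). The ends 0.242, 0.108 and 6.14e-11 are against Dnmt3b_KO as the reference, chosen after seeing the data.

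**Figure D3:**
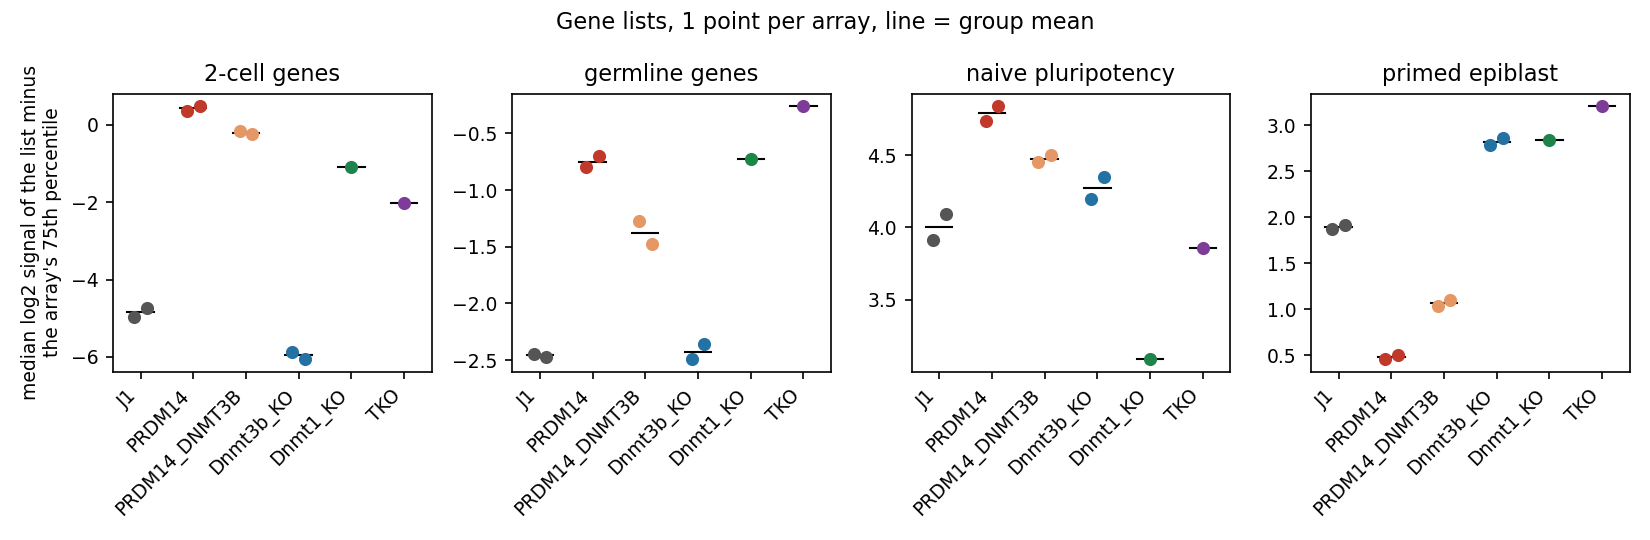
Median log2 signal (y axis) of the genes of the 2-cell, germline, naive pluripotency and primed epiblast lists in the 6 groups (x axis), with 1 point for each of the 10 arrays. The 2-cell list differed from J1 by a median of 4.93 in PRDM14 and 4.39 in PRDM14_DNMT3B, or 3.02 and 2.68 with dim genes at their bound.

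Dnmt3b_KO against J1 asked what loss of 1 de novo methyltransferase changes. Col1a1, a collagen, rose 13.1-fold (3.71 log2 units, SE 0.09, 2 arrays each), and Lefty2 and Lefty1, inhibitors of Nodal, rose by 1.97 and 1.77 (limma adjusted p of 0.000198, 0.000647 and 0.000647). Rhox5, Stra8, a meiosis inducer, and Dppa3, a factor of naive cells, fell by 2.43, 2.26 and 1.09 (limma adjusted p of 0.000702, 0.00112 and 0.00528). Of the 25 naive genes that Dppa3 belongs to, 9 rose and 3 fell, 10 and 3 adjusted over the list alone (median 0.05). The list did not pass with camera (adjusted p = 0.0923; adjusted p = 0.239 with an estimated correlation), but did in 5 of 21 alternatives (range 0.000521 to 0.185). Of the tested genes 4996 changed, 2574 higher and 2422 lower, over 2-fold 884 and 554, and 6323 with slide as a block. A fit of only the 2 groups gave 1105 higher and 756 lower. Median centring gave 3654, 2493 higher and 1161 lower. Without J1 replicate 2 the count was 2992, and without Dnmt3b_KO replicate 1 or 2 it was 2452 or 2457.

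Of 14 fibroblast genes 10 rose and 0 fell in Dnmt3b_KO, likewise adjusted over the list alone (median 1.34, 1.29 with bounds, 1.4 and 1.37 within slides, adjusted p = 6.17e-08; adjusted p = 0.113 with an estimated correlation). Of 11 Rhox genes 0 rose and 6 fell, 7 adjusted over the list alone (median -1.19, -0.75 with bounds, -1.19 and -1.09 within slides, adjusted p = 0.00186; adjusted p = 0.239 with an estimated correlation). Of 20 primed epiblast genes 8 rose and 4 fell, 11 and 4 adjusted over the list alone (median 0.4, 0.3 with bounds, 0.42 and 0.3 within slides, adjusted p = 0.000711; adjusted p = 0.113 with an estimated correlation). Of 14 germ cell specification genes 6 rose and 1 fell, 7 and 1 adjusted over the list alone (adjusted p = 0.00346; adjusted p = 0.14 with an estimated correlation), with Prdm1, a factor of germ cell fate, rising by 1.55. Of 21 primitive endoderm genes 6 rose and 1 fell, likewise adjusted over the list alone (adjusted p = 0.0114; adjusted p = 0.227 with an estimated correlation), and the call ended in 3 of 21 alternatives (range 0.000679 to 0.0855), without J1 replicate 1 among them (adjusted p = 0.061). In the 2-cell list 3 of 18 genes fell (adjusted p = 0.0353; adjusted p = 0.506 with an estimated correlation; 0.255 without J1 replicate 2, 0.168 without Dnmt3b_KO replicate 2 and 0.0573 without either PRDM14_DNMT3B replicate), a call that ended in 12 of 21 alternatives (range 0.002 to 0.255; 0.121 with slide as a block). Among 46 germline genes 11 rose and 9 fell, 13 and 15 adjusted over the list alone, and the list did not pass (adjusted p = 0.869), its median of -0.16 (-0.05 with bounds) and mean of -0.01 being negative and the test positive.

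Dnmt1_KO against J1 asked what loss of maintenance methylation changes. Genes bright only on the lone Dnmt1_KO array passed the filter, which favours genes higher in Dnmt1_KO, and its share in the 2-fold balance below was not tested. H19, an imprinted RNA, was 599-fold higher (9.23 log2 units, SE 0.20, 1 array against 2), and germline genes Fkbp6 and Smc1b, a meiotic cohesin, rose by 5.22 and 4.19 (limma adjusted p of 0.000124, 0.000183 and 0.000169). Naive factors Tfcp2l1, Tcl1 and Gbx2 fell by 1.54, 1.46 and 1.38 (limma adjusted p of 0.00712, 0.00161 and 0.00187). Dnmt3a rose by 0.81 (limma adjusted p = 0.00639). Of the tested genes 6707 changed, 3128 higher and 3579 lower, with 8306 under a slide block, but over 2-fold the balance turned, with 1932 higher and 757 lower. Normexp with quantile normalization gave 6060, 3442 higher and 2618 lower, median centring gave 5488, 2492 higher and 2996 lower, and a fit of only the 2 groups gave 946, 838 higher and 108 lower.

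Of 46 germline genes 33 rose and 1 fell in Dnmt1_KO, 34 and 1 adjusted over the list alone (median 1.73, 1.55 with bounds, 1.66 within slide 1, adjusted p = 2.53e-17), and this call held with an estimated correlation (adjusted p = 0.0283). In the 2-cell list 12 of 18 genes rose and 2 fell, 15 and 2 adjusted over the list alone (median 3.37, 1.74 with bounds, adjusted p = 9.67e-09; adjusted p = 0.108 with an estimated correlation). Of 25 naive genes 1 rose and 15 fell, 1 and 17 adjusted over the list alone (median -0.66, adjusted p = 6.78e-05; adjusted p = 0.0729 with an estimated correlation). Of 21 primitive endoderm genes 11 rose and 2 fell, 11 and 3 adjusted over the list alone (median 0.84, 0.77 with bounds, adjusted p = 9.72e-05; adjusted p = 0.0942 with an estimated correlation). Of 15 trophoblast genes 7 rose and 1 fell, 8 and 1 adjusted over the list alone (adjusted p = 0.00145; adjusted p = 0.0942 with an estimated correlation). Of 14 fibroblast genes 7 rose and 1 fell, 8 and 1 adjusted over the list alone (median 0.89, 0.58 with bounds, adjusted p = 0.000159; adjusted p = 0.108 with an estimated correlation). Against Dnmt3b_KO, a reference chosen after seeing the data, this median was -0.52 and the list passed in the opposite direction (1 rose and 6 fell, adjusted p = 0.0366; adjusted p = 0.265 with an estimated correlation). Over the alternatives that kept the direction the adjusted p of the fibroblast list ran from 3.01e-06 to 0.00115. Rhox genes (5 rose and 1 fell of 11, 6 and 1 adjusted over the list alone) and imprinted genes (13 and 7 of 32, 15 and 10 adjusted over the list alone) passed with adjusted p of 0.00745 and 0.0143, and adjusted p of 0.199 and 0.126 with an estimated correlation. Primed epiblast and Polycomb genes passed with adjusted p of 0.0303 and 0.0442 (adjusted p of 0.128 and 0.386 with an estimated correlation), which became 0.0671 without J1 replicate 1 and 0.159 without J1 replicate 2, and the Polycomb call also ended without either Dnmt3b_KO replicate (0.0562). The primed and Polycomb calls ended in 3 and 12 of 21 alternatives (ranges 0.00264 to 0.728 and 0.0218 to 0.216; 0.207 for Polycomb with slide as a block). The upper end of both ranges is against Dnmt3b_KO as the reference. Germ cell specification genes did not pass (adjusted p = 0.0577; 0.0498 without either PRDM14 replicate), but did in 10 of 21 alternatives (range 0.00503 to 0.4).

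TKO against J1 asked what loss of all 3 enzymes changes. Genes bright only on the lone TKO array passed the filter, which favours genes higher in TKO, and its share in the 2-fold balance below was not tested. Germline genes Fkbp6 and Smc1b rose by 5.63 and 4.34 log2 units (SE 0.20 and 0.13, 1 array against 2), Cubn, an endocytic receptor of endoderm, by 5.16 and Lefty2 by 3.24 (limma adjusted p of 0.000206, 0.000206, 0.000383 and 0.000206). Cdx2, a trophoblast factor, fell by 3.20 and Tfcp2l1 by 1.60 (limma adjusted p of 0.000577 and 0.00562). Of the tested genes 6792 changed, 3303 higher and 3489 lower, 7380 with slide as a block, but over 2-fold the balance turned, with 1993 higher and 1058 lower. A fit of only the 2 groups gave 1113, 863 higher and 250 lower.

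Of 46 germline genes 34 rose and 2 fell in TKO, 35 and 2 adjusted over the list alone (median 2.01, 1.56 with bounds, also 2.01 within slide 1, adjusted p = 4.69e-18), and of 21 primitive endoderm genes 16 rose and 1 fell, 17 and 1 adjusted over the list alone (median 1.63, 1.3 with bounds, adjusted p = 5.46e-09). Both calls held with an estimated correlation (adjusted p of 0.0261 and 0.0394). Of 20 primed epiblast genes 9 rose and 1 fell, likewise adjusted over the list alone (median 0.47, 0.36 with bounds, adjusted p = 0.00134; adjusted p = 0.0946 with an estimated correlation). In the 2-cell list 11 of 18 genes rose and 4 fell, likewise adjusted over the list alone (median 2.36, 0.72 with bounds, adjusted p = 0.00176; adjusted p = 0.33 with an estimated correlation), and the call ended with probes above background on all 10 arrays (adjusted p = 0.141, range 1.28e-06 to 0.141). Of 15 trophoblast genes 0 rose and 9 fell, likewise adjusted over the list alone (median -0.67, adjusted p = 0.0023; adjusted p = 0.101 with an estimated correlation). Imprinted and fibroblast genes passed with adjusted p of 0.0449 and 0.0473 (adjusted p of 0.242 and 0.332 with an estimated correlation), which became 0.0669 and 0.0934 without J1 replicate 1, and 0.0604 and 0.0646 without either Dnmt3b_KO replicate. The fibroblast call also ended without J1 replicate 2 (0.0547), and against Dnmt3b_KO the fibroblast median was -0.81. That is a call in the opposite direction (adjusted p = 0.000132; adjusted p = 0.121 with an estimated correlation). In the direction of the rise, the imprinted and fibroblast calls ended in 7 and 8 of 21 alternatives (ranges 0.0108 to 0.0867 and 0.00667 to 0.0934), quantile normalization (0.0522 each) and the fit of 2 groups (0.0867 each) among them. Of 25 naive genes 5 rose and 7 fell, and the list did not pass (adjusted p = 0.941).

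**Figure D4:**
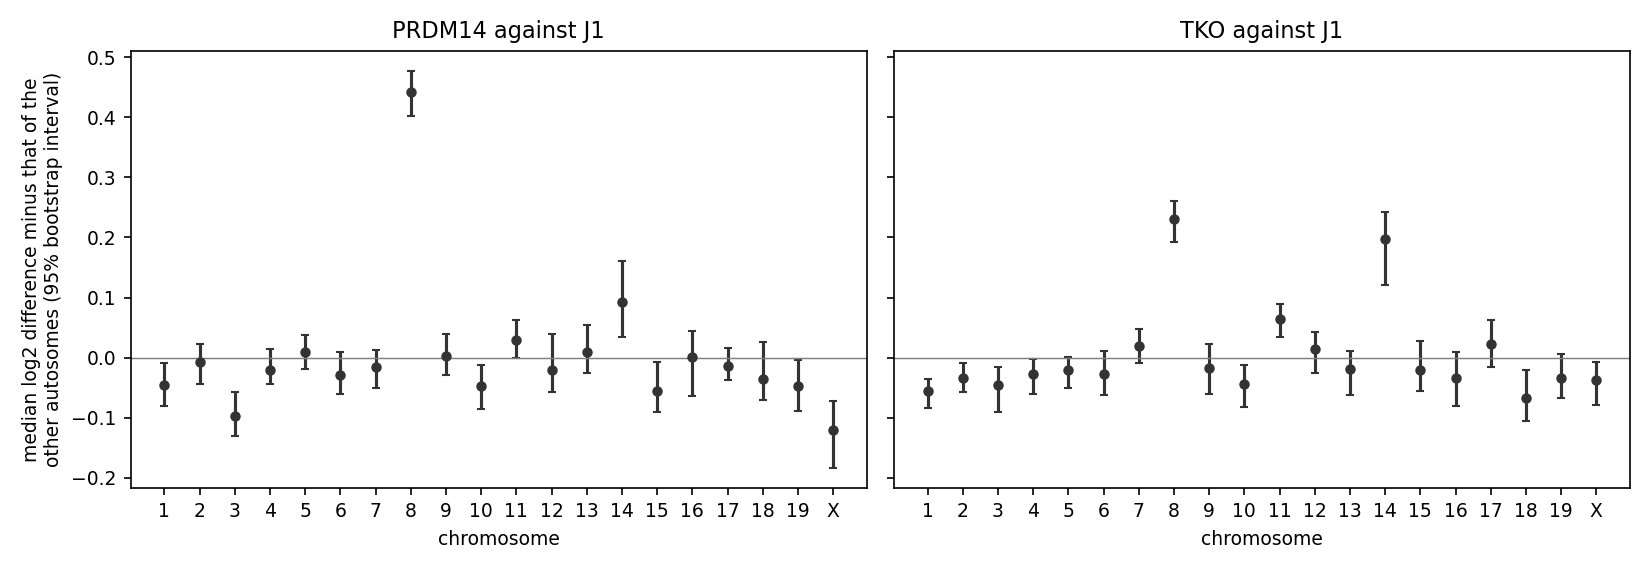
Median log2 difference of the genes of each chromosome (x axis) minus that of the other autosomes (y axis, log2 units) in PRDM14 against J1 and TKO against J1, with points at the medians and lines for bootstrap intervals. Chromosome 8 lay at 0.443 in PRDM14 and 0.23 in TKO.

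Overexpression was compared directly with each knockout, with no J1 value in the difference, though the J1 arrays still enter the variance of the fit. Genes bright only on the lone Dnmt1_KO or TKO array passed the filter here too. Its share in the 2-fold balances against these knockouts was not tested. Against Dnmt3b_KO, Col1a1 fell by 6.07 log2 units in the PRDM14 line and Lefty1 fell by 4.3 (limma adjusted p of 8.62e-06 and 9.51e-06), and Rhox9 rose by 3.39 and Dppa3 by 2.18 (SE 0.10 and 0.14, 2 arrays each). In all 8891 genes differed, 5159 higher and 3732 lower, over 2-fold 1759 and 1800, and 5736 or 5862 without PRDM14 replicate 1 or 2. Of 14 fibroblast genes 14 fell, of 46 germline genes 30 rose and 0 fell, and of 20 primed epiblast genes 2 rose and 12 fell, likewise adjusted over the list alone (adjusted p of 7.57e-11, 7.93e-08 and 5.58e-06; adjusted p = 0.047 for each with an estimated correlation). Of 18 genes of the 2-cell list 16 rose (adjusted p = 2.38e-12; adjusted p = 0.0547 with an estimated correlation), of 25 naive genes 15 rose (adjusted p = 0.00031; adjusted p = 0.0537 with an estimated correlation) and of 11 Rhox genes 8 rose (adjusted p = 0.00118; adjusted p = 0.165 with an estimated correlation), none of these fell, and counts adjusted over the list alone were the same. Trophoblast genes (4 rose and 9 fell of 15, 4 and 10 adjusted over the list alone) and primitive endoderm genes (3 and 10 of 21, 4 and 10 adjusted over the list alone) passed with adjusted p of 0.000816 and 0.0031, and adjusted p of 0.0547 and 0.103 with an estimated correlation. Passing by less, p53 and stress and mesoderm genes had adjusted p of 0.0343 and 0.0498 (adjusted p of 0.147 and 0.166 with an estimated correlation), and the mesoderm call ended without PRDM14 replicate 1 or 2 (0.0583 or 0.0626) and without Dnmt3b_KO replicate 1 or 2 (0.0547 or 0.0655). These calls ended in 1 and 11 of 20 alternatives (ranges 0.0076 to 0.0738 and 0.0141 to 0.227). Imprinted genes did not pass (adjusted p = 0.0969), but did in 3 of 20 alternatives (range 0.0286 to 0.205), without Dnmt3b_KO replicate 1 among them (0.0374).

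Against Dnmt1_KO, the PRDM14 line was higher in Tcl1, Gbx2 and Klf2, naive factors that rose by 3.24, 2.45 and 2.33 log2 units (SE 0.14, 0.13 and 0.10, 2 arrays against 1), and H19 fell by 5.70. In all 9895 genes differed, 5867 higher and 4028 lower, but over 2-fold the balance turned, with 2277 higher and 2701 lower. Of 25 naive genes 22 rose and 0 fell, 23 adjusted over the list alone (median 1.49, adjusted p = 3.13e-09; adjusted p = 0.0372 with an estimated correlation). Among 46 germline genes 5 rose and 18 fell, 6 and 18 adjusted over the list alone (adjusted p = 0.00263; adjusted p = 0.123 with an estimated correlation). Of 14 fibroblast genes 1 rose and 11 fell, likewise adjusted over the list alone (adjusted p = 3.2e-06; adjusted p = 0.0647 with an estimated correlation), and of 18 genes of the 2-cell list 14 rose, 15 adjusted over the list alone (adjusted p = 1.83e-05; adjusted p = 0.147 with an estimated correlation). Primitive endoderm genes (2 rose and 11 fell of 21, 2 and 12 adjusted over the list alone), trophoblast genes (1 and 9 of 15, likewise adjusted over the list alone), primed epiblast genes (4 and 13 of 20, likewise) and imprinted genes (6 and 15 of 32, 6 and 16 adjusted over the list alone) passed with adjusted p of 3.76e-05, 5.8e-05, 0.000187 and 0.00139. With an estimated correlation these became adjusted p of 0.0627, 0.0627, 0.0627 and 0.0718. Mesoderm and p53 and stress genes passed with adjusted p of 0.0417 each (adjusted p = 0.148 with an estimated correlation), which became 0.0657 and 0.0654 without either J1 replicate and ended in 8 and 5 of 19 alternatives (ranges 0.0171 to 0.311 and 0.0125 to 0.0717). Polycomb genes did not pass (adjusted p = 0.0842; 0.0394 without PRDM14 replicate 1, range 0.0163 to 0.245).

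Against TKO, Tbx3, Tcl1 and Fbxo15 rose by 2.34, 2.39 and 2.17 log2 units in the PRDM14 line (SE 0.15, 0.14 and 0.14, 2 arrays against 1), Tfap2c, a germ cell and trophoblast factor, rose by 3.25, and Lefty1 was 31.9-fold lower. In all 8557 genes differed, 4790 higher and 3767 lower, but over 2-fold the balance turned, with 1850 higher and 2404 lower. Of 25 naive genes 20 rose and 0 fell, of 20 primed epiblast genes 2 rose and 14 fell, likewise adjusted over the list alone, and of 21 primitive endoderm genes 0 rose and 17 fell, 1 and 17 adjusted over the list alone (adjusted p of 5.94e-08, 2.25e-07 and 5.87e-09; adjusted p = 0.0258 for each with an estimated correlation). Among 46 germline genes 3 rose and 21 fell, likewise adjusted over the list alone (adjusted p = 9.32e-06; adjusted p = 0.0584 with an estimated correlation). Of 18 genes of the 2-cell list 16 rose, 17 adjusted over the list alone (adjusted p = 5.87e-09; adjusted p = 0.0746 with an estimated correlation). Imprinted genes (5 rose and 18 fell of 32, 6 and 18 adjusted over the list alone) and fibroblast genes (1 and 9 of 14, 1 and 10 adjusted over the list alone) passed with adjusted p of 0.000247 and 1.75e-05, and adjusted p of 0.0584 and 0.0746 with an estimated correlation. Trophoblast and germ cell specification genes passed with adjusted p of 0.0332 each (adjusted p = 0.129 with an estimated correlation), and ended in 7 and 6 of 19 alternatives (ranges 0.0139 to 0.221 and 0.00937 to 0.0966). Quantile normalization ended both (0.0728 and 0.0537), and leaving out either J1 replicate ended the trophoblast call (0.0566). Polycomb genes did not pass (adjusted p = 0.11; 0.0429 without PRDM14 replicate 1, range 0.0258 to 0.468).

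Overlap with PRDM14 against J1 was counted in the same direction. PRDM14_DNMT3B against J1 shared 3416 higher and 2919 lower genes, where independent lists would share 974 and 873. Dnmt3b_KO shared 1554 and 1093 (independent lists 540 and 452), Dnmt1_KO 1353 and 1130 (656 and 668), and TKO 1750 and 1475 (693 and 652). Genes changed in opposite directions numbered 266 in PRDM14_DNMT3B (independent lists 1847), 718 in Dnmt3b_KO (989), 1341 in Dnmt1_KO (1335) and 899 in TKO (1349). Differences from J1 correlated with those of PRDM14 at r of 0.81, 0.29, 0.21 and 0.36, where simulated unchanged groups of independent arrays sharing the J1 arrays gave 0.5, 0.5, 0.41 and 0.41. Their covariances were 0.775, 0.18, 0.2 and 0.341 against 0.038 in that simulation. The arrays were not independent: differences between replicates correlated at 0.26 to 0.51 between groups. In simulations chosen after seeing the data, the correlations were 0.37, 0.37, 0.27 and 0.27 with arrays of 1 slide correlated and 0.5, 0.5, 0.35 and 0.35 with arrays of 1 replicate number correlated, and the covariances 0.021 and 0.019. None of these simulations held group effects, which widen the spread that a correlation divides by. An observed correlation under a simulated one therefore does not show less overlap than shared J1 arrays give. The J1 arrays are too few to split, so a difference of the J1 line itself enters every overlap. The overlap for Dnmt3b_KO was 1684 without J1 replicate 2 and 1456 or 1413 without Dnmt3b_KO replicate 1 or 2, and that for Dnmt1_KO was 1637 or 1654 without PRDM14 replicate 1 or 2.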

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

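The reference of Dnmt3b_KO arrays in place of J1 and the lists without chromosome 8 genes were chosen after seeing the data, and the other alternatives before. Of 162 list results, 146 counted as kept with probes above background on all 10 arrays, where 12 calls ended. Without a filter 148 were kept, with quantile normalization 150 and with the deposited values 150. A fit of only the 2 groups kept 152, and lists without chromosome 8 genes 153. With slide as a fixed block 69 of 72 were kept, with a block for replicate number 85 of 90, and with Dnmt3b_KO as the reference 54 of 72. A called list counted as kept if it passed in the same direction. An uncalled list counted as kept if it did not pass or if its direction turned, so uncalled lists may have changed direction. The variance prior that follows signal kept 162, which was fixed in advance because the list test does not use that prior. It is still counted among the alternatives of each list. Genes with dim signal have bounds in place of folds.

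Without a filter on dim probes the counts were 2993 (PRDM14_DNMT3B against PRDM14), 2995 (Dnmt3b_KO against J1) and 4081 (Dnmt1_KO against J1), and the overlaps with PRDM14 were 1664 and 1471 for those knockouts. The cause was not tested. A 2-fold minimum, which can only lower a count, gave 3986, 1514, 3924, 1438, 2689 and 3051 for PRDM14, PRDM14_DNMT3B against PRDM14, PRDM14_DNMT3B, Dnmt3b_KO, Dnmt1_KO and TKO, 3559, 4978 and 4254 for PRDM14 against the 3 knockouts, and overlaps of 2529, 680, 813 and 1171. In a fit of only the 2 groups, with fewer arrays for the spread, the counts were 1861 (Dnmt3b_KO), 946 (Dnmt1_KO) and 1113 (TKO). With slide as a random block they were 8455 (Dnmt3b_KO) and 10095 (Dnmt1_KO), with a correlation within slides of 0.456, and the cause was not tested.

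Usp17la in Dnmt1_KO turned to -0.39 with quantile normalization and -0.33 with probes above background on all 10 arrays, where Synm in Dnmt3b_KO turned to -0.1. The probe with the highest mean was chosen anew in each setting, so these values may be of other probes. In the main fit Usp17la was at -6.24 and -6.14 in J1 and -0.78 in Dnmt1_KO. The turns are therefore not read as reversals of the same signal, and the probes used were not compared. With Dnmt3b_KO as the reference, PRDM14 turned to -0.13 for Dnmt3a, 3.37 for Dnmt3b, -0.05 for Trdmt1, -0.03 for Tbx3, -1.35 for Plagl1 and -0.17 for Hprt, and PRDM14_DNMT3B to 2.47 for Dnmt3b and 0.21 for Rhox5. Dnmt1_KO turned to -0.52 for the fibroblast list, -0.57 for Hprt, 0.42 for Mid1 and -0.01 for Lefty1, with 3985 genes changed. TKO turned to -0.81 for the fibroblast list, -0.32 for Prdm14, 0.33 for Dnmt3b, -0.43 for Hprt, -0.61 for Fas and -0.13 for Fbln2, with 4301 genes changed. The Dnmt3b values follow from the knockout of the reference, and for the others the cause was not tested.

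With 1 array left out, the lone array being assumed to vary like the other groups, counts ran from 6449 to 8915 (PRDM14 against J1), 1909 to 4700 (PRDM14_DNMT3B against PRDM14), 7010 to 8554 (PRDM14_DNMT3B against J1), 2452 to 4133 (Dnmt3b_KO), 4473 to 5849 (Dnmt1_KO), 4814 to 5979 (TKO), and 5736 to 8807, 7170 to 9853 and 5916 to 8505 for PRDM14 against Dnmt3b_KO, Dnmt1_KO and TKO. The overlaps ran from 4808 to 5764 (PRDM14_DNMT3B), 1413 to 2250 (Dnmt3b_KO), 1637 to 2141 (Dnmt1_KO) and 2297 to 2861 (TKO). With a block for the pairing by replicate number, 11421, 7017, 10993, 7153 and 10816 genes changed in PRDM14 against J1, PRDM14_DNMT3B against PRDM14 and J1, Dnmt3b_KO against J1 and PRDM14 against Dnmt3b_KO. Not run were list tests with slide as a random block, a fixed slide block for PRDM14, a replicate block for Dnmt1_KO and TKO, and leaving out their lone arrays. A block for scan day equals that for slide.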

Other observations

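The tests of slide and of labelling of the J1 arrays, of shared methylation loss, of array scaling, of the chromosome 8 median and of slide for the 2-cell genes were chosen only after the result was seen, and the other 4 before it.

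Hprt and further genes parted both J1 arrays from the other 8. Counted at 2-fold or more, 256 genes parted J1 from each of the 5 other groups. Among the other groups of 2 arrays, such counts were 381 for PRDM14, 238 for PRDM14_DNMT3B and 74 for Dnmt3b_KO. A set of this size is therefore not particular to J1. For Hprt itself slide or scan is argued against, as the arrays of other groups on the 2 J1 slides exceeded J1 in Hprt by 8.16 log2 units or more. Within the scan pass of J1 on slide 1, Hprt was at -2.35 in J1, 6.33 in PRDM14_DNMT3B and 6.27 in Dnmt3b_KO. This covers Hprt only and says nothing of the further genes. Weak labelling of whole J1 arrays is argued against for it too, since the 75th percentile of unscaled signal differed by 0.47 log2 units between the lowest J1 array and the highest other array. Direct derepression by methylation loss in the 5 other groups would leave nearly all of the 256 genes parting J1 lower in J1, and 178 were, but 30.5% (24.9 to 36.5) were higher, which argues against it as the cause of the whole set and leaves it open for the lower genes. Whether J1 held RNA of a line of another origin stays open: 6 genes had 1 probe parting J1 beside one that did not, against 8 in the highest other group of 2 arrays (exact binomial p = 0.791).

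Genes of chromosome 8 lay higher in PRDM14 than in J1. An extra copy of the chromosome may explain this, as the lowest of its 4 parts of equal gene number lay at 0.403, and DNA copy number was not analysed here. For a few strongly changed genes the test set beforehand left the matter open, with 71.9% of 1003 genes (69 to 74.6) above the median of the other autosomes and a bound of over 70, while the median of 0.443 (0.403 to 0.478), a test chosen after, argues against them. A constant shift of an array cancels in these values, and scaling that follows signal level is argued against by a lowest value of 0.341 under the other scalings.

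PRDM14 arrays lay on slides of their own. Of 8891 genes differing between PRDM14 and Dnmt3b_KO, 71.5% had the same direction in PRDM14_DNMT3B against J1, short of the bound of over 80 set beforehand. The share was 80.7% among genes over 2-fold, and 66% went the same way on both slides. Slide alone was predicted beforehand to give an even split, and the share of all 8891 genes lay between that and the bound. A slide effect and an effect of PRDM14 therefore cannot be told apart for these genes. Slide as the source of the 2-cell rise is argued against by PRDM14_DNMT3B, which lay on slides with J1 and had within-slide medians of 4.47 and 4.32, with 2.68 over both slides when dim genes are at their bound.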
